A study of Homo sapiens with 6 samples.

How the data were processed

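RNA was measured by sequencing in 6 libraries, 3 from wild type HEK293T cells and 3 from HEK293T cells with a CRISPR/Cas9 double knockout of ALKBH5 and FTO. The RNA came from cleared Triton lysates made with cycloheximide, and the labels call it cytoplasmic. The amount of nuclear RNA carried over was not determined, but nuclear RNAs were compared between the groups. Ribosomal RNA was depleted and poly(A) RNA was not selected. Per the labels, 1 µg of RNA per library received 7 pg of GFP mRNA and 1.2 pg of FLuc mRNA as spike-in RNAs. The replicates were independent biological replicates per the labels. The number of knockout clones behind the 3 double knockout libraries was not given in the sources used here.

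The authors trimmed reads with cutadapt 2.10, aligned them with STAR 2.7.6a to the human genome (hg38) and counted them per gene with featureCounts, whose version was not given in the sources used here. The deposited values were raw read counts per gene, whole numbers with no normalisation. The table held 58721 genes and 4 spike-in entries, GFP, FLuc, Rluc and Ribo. Its gene identifiers matched GENCODE release 29, which supplied gene symbols, types and positions. The strand setting and the handling of reads with several alignments were not given in the sources used here. A gene that overlaps another gene, and a member of a near-identical family such as the histones, therefore has an uncertain count. Of 125 genes named in the text, 32 overlapped another tested gene. The deposited wild type columns were named HEK293G6, and the labels do not explain G6. Whether these cells were the parental line of the double knockout was not given in the sources used here. The columns were assigned to wild type because no other genotype remained, and to replicates by their number.

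Total gene counts per library lay between 5634648 and 7551825. A count of 0 in a library allows a level of up to 3 counts, which was 0.397 to 0.532 CPM (counts per 1000000 counts). Intervals on counts are exact (Clopper-Pearson) 95% intervals and cover counting error only. Intervals of medians came from resampling genes, and those of ratios and shares of genes were exact binomial intervals over genes. They treat genes as independent and do not cover differences between libraries.

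Expression was compared in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr at its default settings (minimum count 10, minimum total count 15), libraries were scaled by TMM, and a quasi-likelihood model was fitted with glmQLFit in robust mode. glmQLFTest gave two-sided p-values for double knockout against wild type, adjusted by Benjamini and Hochberg over all tested genes with a threshold of 0.05. Log2 fold changes are double knockout over wild type. CPM of genes used TMM-scaled library sizes. A 2-fold change means a fitted log2 fold change of at least 1 in size. Differences of single values between the groups were tested with two-sided exact permutation tests, for which 3 against 3 libraries allow no p below 0.1. Replicate numbers did not pair the libraries: after group means were removed, correlations between libraries of the same number were 0.0106, 0.0166 and 0.0085.

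Before the data were examined, 30 gene lists were fixed. They covered m6A methyltransferases, m6A readers, other AlkB dioxygenases, neighbours of both targeted genes, transcripts described elsewhere as substrates of FTO or ALKBH5, immediate early genes, ATF4 targets, the unfolded protein response, heat shock chaperones and p53 targets. Others were interferon-stimulated genes, G2 and M phase genes, S phase genes, ribosomal proteins, translation factors, cholesterol synthesis, glycolysis and hypoxia, mitochondrial mRNAs, oxidative phosphorylation, replication-dependent histones and nuclear-retained RNAs. The remaining lists were cytoplasmic noncoding RNAs, WNT feedback targets, TGF-beta and BMP targets, clustered protocadherins, numbered zinc finger genes, and neuronal, kidney tubule, fibroblast and haematopoietic markers. The clustered protocadherins had 0 members past the filter and were not tested. Lists and chromosomes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. Adjusted p-values of lists were taken over 29 lists, and those of chromosomes over 24 sets. camera compares a set with the other genes, whereas fry does not.

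The genes to name were fixed by a rule before the data were examined. The rule took ALKBH5 and FTO, then the 10 largest rises and 10 largest falls among changed genes. Such genes needed a mean of at least 50 normalised counts in the higher group and libraries of the groups that did not overlap. It then took the 3 members with the smallest p of each list with a called test or a changed member, and the measured neighbours of both targets. Members of a called list that moved in a direction taken by 5 or fewer members were added after the values were seen.

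Genes were ordered by position on each chromosome and divided into segments of at least 20 genes by a least-squares search on log2 fold changes limited to 1.5 in size (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). A segment was called shifted when its mean differed from the median of all genes by at least 0.2. This mean, of the limited values, was the one subtracted from single genes, whereas segments are described by their medians. The 2 can differ, as with 0.219 and 0.117 for chromosome 13 from 18.2 to 74.0 Mb. Small remainders that turned, such as those of CKAP2 and COX6B1, can depend on this choice. The segment search was written after the chromosome tests had been seen. Its minimum was first 30 genes and was lowered after a shorter stretch of chromosome 3 had been seen. Figures were drawn with matplotlib 3.10.9.

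The steps were tested on simulated data with the observed depths and dispersions. edgeR recovered 26 of 50 genes changed 1.25-fold, 33 of 50 changed 1.5-fold, 46 of 50 changed 2-fold and 50 of 50 changed 4-fold. It called 8 of 13950 unchanged genes, against 1 with DESeq2 and 11 with limma voom. A planted list of 30 genes was called and 0 of 28 random lists were called by camera. Simulated genes were drawn independently, so this could not test the preset correlation on which the list calls rest. In the simulation 13950 of 14180 genes were unchanged, whereas 57.1% of tested genes changed in the data, so recovery there may differ. The segment search recovered planted segments of 200, 100 and 50 genes with shifts of 0.4, 0.5 and 0.6 in all 20 draws. It missed a segment of 60 genes with a shift of 0.3 in all 20 draws.

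The alternatives tried were DESeq2 size factors, total count scaling, spike-in scaling, no filter, a mean CPM of at least 5, protein-coding genes only, and leaving out mitochondrial and the 20 most abundant genes. Others were replicate number as a block, glmQLFit without robust mode, an adjusted p under 0.01, glmTreat against a 1.2-fold change, limma voom, the DESeq2 1.42.0 Wald test, an estimated correlation and leaving out each library. Spike-in scaling with Rluc, leaving out chromosomes 3, 4 and 9, and leaving out shifted segments were added after seeing the data.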

Results

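The data were read counts per gene from 6 RNA sequencing libraries of cytoplasmic RNA without poly(A) selection. 3 libraries came from wild type HEK293T cells, a human embryonic kidney line, per the labels. Their columns were named HEK293G6, and whether these cells were the parents of the double knockout was not given in the sources used here. A difference between lines was not separated from the knockout. The other 3 came from HEK293T cells with a double knockout of ALKBH5 and FTO, which encode demethylases of N6-methyladenosine (m6A) in RNA. Total gene counts were 7400110, 7551825 and 5634648 in wild type replicates 1 to 3, and 5923328, 6433469 and 6136806 in double knockout replicates 1 to 3. Protein-coding genes took 95.7% ± 0.0646 of the counts in wild type and 95.3% ± 0.102 in double knockout (SD, n = 3 each). Mitochondrial genes took 2.42% ± 0.00855 and 2.67% ± 0.0771 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Of these, mitochondrial rRNA took 1.41% ± 0.00797 and 1.77% ± 0.0818 (exact p = 0.1). The nuclear RNAs MALAT1 and NEAT1 together had 1665 ± 27.5 and 1682 ± 52.4 CPM (counts per 1000000, exact p = 0.7). Small nuclear and nucleolar RNAs took 0.246% ± 0.0404 and 0.232% ± 0.038 (exact p = 0.7). Libraries of the same group differed little beyond counting error, with chi-square over degrees of freedom of 1.10 to 1.38, against 10.8 to 12.7 between the groups. The first principal component held 75.6% of the variance and separated the groups.

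The double knockout was compared with wild type to ask how loss of both demethylases changes the cytoplasmic transcriptome. Both targeted transcripts were lower in the double knockout but not absent. FTO (ENSG00000140718.20, chromosome 16, 53701692 to 54158512, hg38) had 106, 96.5 and 112 CPM in wild type replicates 1 to 3 and 53.8, 53.6 and 61.0 CPM in the double knockout replicates. FTO fell by 0.90 on the log2 scale (SE 0.06, adjusted p = 4.00e-44), from 105 ± 7.83 to 56.1 ± 4.21 CPM (SD, n = 3 each). ALKBH5 (ENSG00000091542.8, chromosome 17, 18183078 to 18209954) had 243, 256 and 235 CPM in wild type and 186, 186 and 187 CPM in double knockout. ALKBH5 fell by 0.40 (SE 0.04, adjusted p = 2.74e-22), from 245 ± 10.3 to 186 ± 0.599 CPM. Counts of whole genes do not show whether the remaining transcripts carried edits. FTO overlaps RPGRIP1L on the opposite strand, and the strand setting of the counts is not known.

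**Figure D1:**
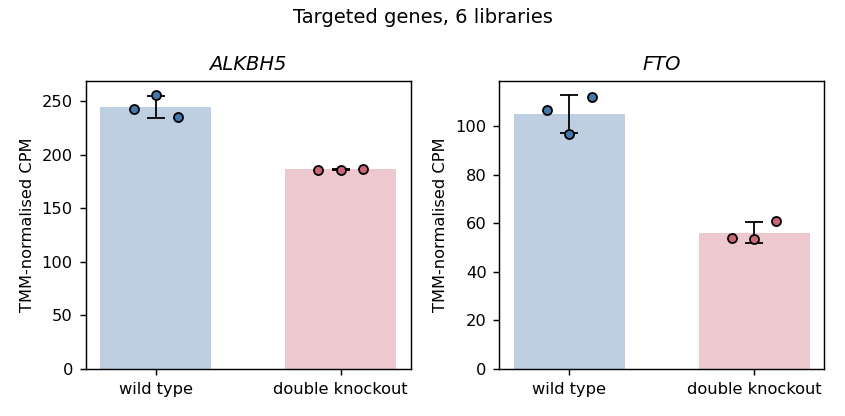
TMM-normalised CPM (y axis, from 0) of ALKBH5 and FTO in each of the 6 libraries, by group; bars are means and error bars are SD over 3 libraries. All double knockout libraries lay below all wild type libraries for both genes, with means of 186 against 245 CPM for ALKBH5 and 56.1 against 105 CPM for FTO.

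Genes beside the targeted loci moved in both directions. Of 15 measured neighbours, 5 rose, 2 fell and 8 did not pass, against 4 and 1 adjusted over the list alone, and 1 rose and 2 fell with spike-in scaling. AKTIP rose by 0.52, DRG2 by 0.26, SHMT1 by 0.22, SMCR8 by 0.17 and MYO15A by 0.83 on the log2 scale. CHD9 fell by 0.35 and RPGRIP1L fell by 0.18. The list did not differ from other genes (adjusted p = 0.504). The calls of MYO15A, SMCR8 and RPGRIP1L were lost when single libraries were left out. SMCR8 and SHMT1 overlap each other on opposite strands.

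Across the transcriptome, 8093 of 14180 tested genes changed, 4055 higher and 4038 lower in the double knockout, which is 57.1% of those tested. Most changes were small: 5567 of the changed genes (68.8%) moved by less than 1.5-fold, and the median size of a change was 0.40 on the log2 scale. Among changes of at least 2-fold, 657 genes rose and 194 fell. The groups did not overlap in 8590 genes (60.6%), against the 10% that chance gives for 3 against 3 libraries. The small spread between replicates, a common biological coefficient of variation of 2.40%, let changes as small as 0.06 pass. With DESeq2 3027 genes rose and 3138 fell, and limma voom gave 4007 and 4010.

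Some of the largest rises were in genes scarcely expressed in wild type. MMP12, a secreted elastase, rose by 5.63 on the log2 scale (SE 0.33, adjusted p = 2.36e-52), from 0.243 ± 0.053 to 13.2 ± 0.731 CPM (SD, n = 3 each), with 5 counts over the wild type libraries. SCARA5, a scavenger receptor, rose by 4.59, ZNF257 by 4.23, the tyrosine kinase SYK by 3.64 and the matrix protein TNC by 3.63. KIF1A, a motor of axonal transport, rose by 3.35 (SE 0.07, adjusted p = 1.52e-206), from 15.9 ± 2.15 to 160 ± 2.45 CPM. FGF13 rose by 3.13, TMEM271 by 3.01, OAS3 by 3.01 and the potassium channel gene KCNH2 by 2.99. The largest fall was in EPDR1, with 352 counts over the wild type libraries and 3 over the double knockout libraries, a ratio of 109 (95% counting interval 37.1 to 532). The long noncoding RNA AC015522.1 changed by -4.18, STEAP1B by -3.54, SERPINF1 by -3.21 and TENM1 by -2.81. CA2, a carbonic anhydrase, changed by -2.52, the retinoic acid receptor gene RARB by -2.46, the transcription factor gene MAF by -2.31, BEX5 by -2.24 and CPS1 by -2.18. SYK and TNC (chromosome 9), TMEM271 (chromosome 4), KCNH2 (chromosome 7), ZNF257 (chromosome 19), EPDR1 and STEAP1B (chromosome 7) and RARB (chromosome 3) lie in chromosome segments that moved in the same direction. Those segments moved by far less than these genes. TENM1 and RARB overlap genes on the opposite strand.

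Of 17 measured m6A readers and their decay partners, 11 fell, 3 rose and 3 did not pass, also when adjusted over the list alone. YTHDC1, the nuclear m6A reader, fell by 0.71, HNRNPA2B1 fell by 0.39, and CNOT1, the scaffold of the deadenylase complex, fell by 0.42. The 3 that rose were YTHDF1 (0.22), FMR1 (0.17) and UPF1 (0.11), named after their values were seen. The calls of these 3 genes, ALKBH3 and ALKBH4 were lost without single libraries, and with spike-in scaling these 5 calls were lost as well and UPF1 turned to -0.0022. The list was lower than other genes (median log2 fold change -0.22, camera adjusted p = 0.0217), and adjusted p = 0.172 with an estimated correlation, within a range of 0.00163 to 0.172 over 21 alternatives. With a mean CPM of at least 5 its adjusted p was 0.0645. Of 14 measured m6A methyltransferase genes, 7 fell and 2 rose, with the same counts adjusted over the list alone, and 7 fell and 1 rose with spike-in scaling. METTL14 fell by 0.67, METTL16 fell by 0.51 and WTAP fell by 0.39, and the list did not pass (adjusted p = 0.199), though it did without the low-count filter (0.0463, in a range of 0.0463 to 0.414). Of 6 measured other AlkB dioxygenases, 2 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.953). Their median was 0.02 and their mean -0.01, and camera gave the direction up. ALKBH3 rose by 0.23, ALKBH4 rose by 0.27 and ALKBH8 fell by 0.32. Of 12 measured transcripts described elsewhere as substrates of FTO or ALKBH5, 3 rose, 5 fell and 4 did not pass, against 4 and 7 adjusted over the list alone, and 2 rose and 5 fell with spike-in scaling. CEBPA rose by 1.09, KLF4 rose by 1.42 and CCNA2 fell by 0.83. That list's median was -0.10 and its mean 0.11, camera gave the direction down (adjusted p = 0.806) and fry gave up. YTHDC1, METTL14 and CCNA2 lie on chromosome 4, HNRNPA2B1 and ALKBH4 on chromosome 7, WTAP on chromosome 6, CEBPA and UPF1 on chromosome 19 and KLF4 on chromosome 9, each in a segment that moved in the same direction. With the mean of its segment subtracted, YTHDC1 kept -0.21, METTL14 -0.17, CCNA2 -0.34, HNRNPA2B1 -0.17, CEBPA 0.38 and KLF4 1.01. WTAP (0.02), ALKBH4 (0.01) and UPF1 (-0.09) kept little or turned.

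Immediate early genes, which respond quickly to growth and stress signals, were higher in the double knockout. Of 26 measured, 20 rose, 2 fell and 4 did not pass, the same adjusted over the list alone, and 10 rose by at least 2-fold. JUN rose by 1.18 (from 201 ± 3.43 to 456 ± 3.57 CPM, SD, n = 3 each), ATF3 by 1.22 and JUND by 1.01. FOSB fell by 0.97 and MYC fell by 0.16, both named after their values were seen. FOSB had 55 counts over the wild type libraries and 26 over the double knockout libraries, and its call was lost without single libraries. JUND and FOSB lie on chromosome 19, in segments that rose and fell, respectively. The list was higher than other genes (median 0.77, adjusted p = 3.08e-05). The test gave adjusted p = 0.139 with an estimated correlation, the highest of a range that began at 7.73e-08 over 21 alternatives.

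Targets of ATF4, a transcription factor of amino acid and stress responses, were lower. Of 34 measured, 19 fell, 4 rose and 11 did not pass, the same adjusted over the list alone. The cystine transporter gene SLC7A11 fell by 1.74 and DDIT4, an inhibitor of mTORC1, fell by 1.56. The 4 that rose were ATF3 (1.22), PPP1R15A (0.57), TRIB3 (0.53) and CEBPG (0.40), the last 3 named after their values were seen. The list median was -0.22 (adjusted p = 0.00245), with adjusted p = 0.139 with an estimated correlation and a lowest value of 1.32e-07 among the alternatives. SLC7A11 lies in the part of chromosome 4 that fell, and CEBPG in the part of chromosome 19 that rose. PPP1R15A rose in a part of chromosome 19 that fell. With the segment mean subtracted, SLC7A11 kept -1.24 and PPP1R15A 0.84, while CEBPG turned to -0.32.

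Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, were lower. Of 43 measured, 35 fell, 3 rose and 5 did not pass, the same adjusted over the list alone, and 35 fell and 2 rose with spike-in scaling. HIST2H2BE fell by 0.95 (from 301 ± 12.1 to 155 ± 8.90 CPM), HIST1H3H fell by 0.91 and HIST2H2AC fell by 0.88. HIST1H2AE (1.64), HIST1H2BG (1.61) and HIST1H3E (0.43) rose, and these genes, named after their values were seen, lie side by side on chromosome 6 between 26215159 and 26227473. The list median was -0.63 (adjusted p = 1.17e-08). The estimated correlation within the list was 0.586, which gave adjusted p = 0.444 with an estimated correlation, and the alternatives ranged from 1.84e-24 to 0.444. Histone genes are near-identical copies, so reads may be shared between members.

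With TMM and the preset correlation, S phase genes were higher and G2 and M phase genes were lower. These lists were not tested against each other. Of 33 measured S phase and DNA replication genes, 22 rose, 3 fell and 8 did not pass, the same adjusted over the list alone. E2F2 rose by 0.85, SLBP, which binds histone mRNA, by 0.63 and the helicase subunit gene MCM7 by 0.52. MCM2 fell by 0.37, POLD1 fell by 0.40 and ORC1 fell by 0.15, named after their values were seen. The list median was 0.14 (adjusted p = 0.00455), with adjusted p = 0.139 with an estimated correlation and 0.0644 with spike-in scaling (median 0.034), in a range that began at 1.41e-04. Of 31 measured G2 and M phase genes, 19 fell, 4 rose and 8 did not pass, against 20 and 4 adjusted over the list alone. The centromere protein genes CENPE and CENPF fell by 1.58 and 0.62, and ECT2, needed for cytokinesis, fell by 0.82. HMMR (0.33), CKAP2 (0.16), TACC3 (0.15) and BUB3 (0.11) rose, named after their values were seen. The calls of ORC1, TACC3 and BUB3 were lost without single libraries. The list median was -0.18 (adjusted p = 0.00129), with adjusted p = 0.172 with an estimated correlation and a lowest value of 5.06e-06. CENPE (chromosome 4), ECT2 and MCM2 (chromosome 3) and POLD1 (chromosome 19) lie in segments that fell. SLBP and TACC3 (chromosome 4), MCM7 (chromosome 7) and CKAP2 (chromosome 13) lie in segments that rose. With the segment mean subtracted, CENPE kept -1.08, ECT2 -0.31, POLD1 -0.12, SLBP 0.12 and MCM7 0.27. TACC3 (-0.36), MCM2 (0.15) and CKAP2 (-0.06) turned.

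The measured genes of the neuronal and kidney tubule marker lists were higher as sets with the preset correlation. Each list held 22 genes, and those that did not pass the filter were not tested. Of 10 measured neuronal markers, 8 rose and 2 did not pass, the same adjusted over the list alone, and 5 rose with spike-in scaling. The neuronal enolase gene ENO2 rose by 2.03, UCHL1 rose by 1.12 and the neurofilament gene NEFM by 0.82. The list median was 0.71 (adjusted p = 0.00129), with adjusted p = 0.139 with an estimated correlation and a lowest value of 1.43e-05. Of 11 measured kidney tubule markers, 7 rose, 1 fell and 3 did not pass, the same adjusted over the list alone. The endocytic receptor gene LRP2 rose by 1.59 and the keratin genes KRT18 and KRT8 by 0.69 and 0.44. CUBN, whose protein acts with that of LRP2, fell by 0.89 and was named after its value was seen. The list median was 0.69 (adjusted p = 0.0184), with adjusted p = 0.172 with an estimated correlation, 0.0767 with a mean CPM of at least 5, and a lowest value of 0.00388. UCHL1 lies in the part of chromosome 4 that rose and CUBN in the part of chromosome 10 that fell. Haematopoietic markers, 3 measured of 16 listed, had a similar median of 0.58 (camera adjusted p = 0.287), and fibroblast markers had -0.05. Genes were not matched on expression level in camera. A rise of scarce genes in general was therefore not separated from a change of cell type.

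**Figure D2:**
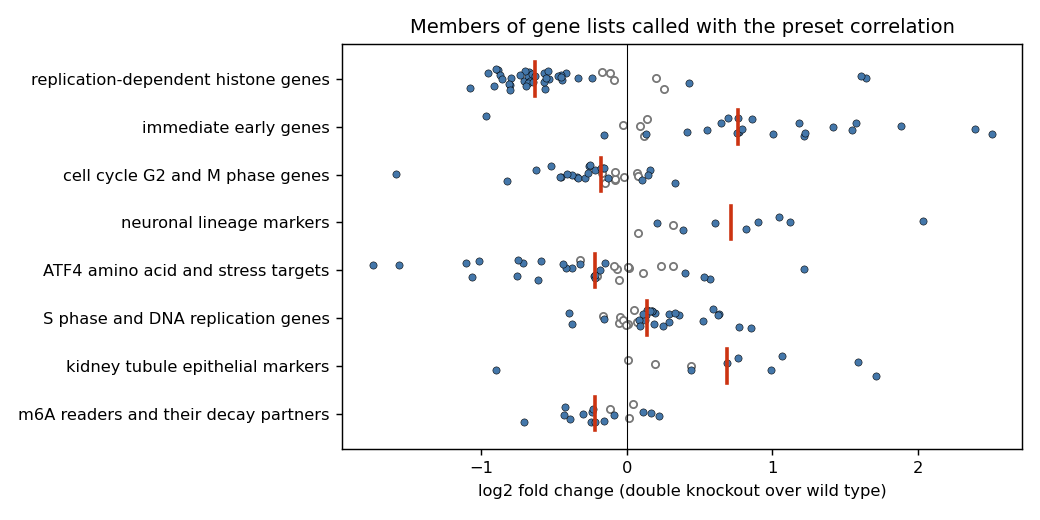
Log2 fold changes (x axis, double knockout over wild type) of the measured members of the 8 gene lists called by camera with the preset correlation. Each point is a gene, filled where it passed the adjusted p threshold, and red bars are list medians. The medians ran from -0.63 for histone genes to 0.77 for immediate early genes.

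The lists of p53 targets, interferon-stimulated genes and nuclear-retained RNAs did not pass as sets, though single members changed. Of 27 measured p53 targets, 12 rose and 6 fell, against 13 and 7 adjusted over the list alone, and 7 rose and 6 fell with spike-in scaling. The cell cycle inhibitor gene CDKN1A rose by 1.71, the proapoptotic gene PMAIP1 by 1.56 and GADD45A by 0.96 (list adjusted p = 0.181). The list passed in 1 of 21 alternatives, with DESeq2 (0.0226), in a range of 0.0226 to 0.310. Of 18 measured interferon-stimulated genes, 9 rose and 2 fell, against 10 and 2 adjusted over the list alone, and 5 rose and 2 fell with spike-in scaling. OAS3 rose by 3.01, IFITM3 rose 2.83-fold, and HERC5, in the part of chromosome 4 that fell, fell by 1.34. The interferon list missed the threshold (adjusted p = 0.0588) but passed in 10 of 21 alternatives, in a range of 0.0211 to 0.235. Of 12 measured nuclear-retained RNAs, 6 fell and 6 did not pass, the same adjusted over the list alone, and 8 fell with spike-in scaling. KCNQ1OT1 fell by 0.85, PVT1 fell by 0.54 and TUG1 fell by 0.42. That list missed the threshold (adjusted p = 0.0588) and passed in 7 of 20 alternatives, in a range of 0.0239 to 0.494.

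Genes of whole chromosome parts moved together. Of 787 tested genes of chromosome 3, 531 fell and 53 rose (median -0.44, adjusted p = 1.96e-19), and 535 fell and 56 rose adjusted over the list alone. Of 588 genes of chromosome 9, 329 rose and 65 fell (median 0.24, adjusted p = 2.43e-08), and 336 rose and 66 fell adjusted over the list alone. Of 548 genes of chromosome 4, 264 fell and 166 rose (median -0.28, adjusted p = 0.0117), and 269 fell and 174 rose adjusted over the list alone. These calls passed with an estimated correlation, at 5.14e-04, 0.00123 and 0.0357. Over their alternatives the adjusted p ranged from 1.76e-24 to 0.910, from 6.41e-10 to 0.910 and from 5.54e-04 to 0.414, respectively. Chromosomes 3 and 9 lost their calls only without shifted segments, and chromosome 4 only without the low-count filter (median -0.0020 relative to all genes). Without shifted segments chromosome 4 had no tested genes left. On chromosome 12, 264 of 746 genes rose and 130 fell, and on chromosome 11, 269 of 758 rose and 141 fell (adjusted p = 0.0489 each). Adjusted over the list alone, 261 rose and 129 fell on chromosome 12, and 267 rose and 140 fell on chromosome 11. The calls of chromosomes 11 and 12 passed in 8 and 9 of 21 alternatives, with ranges of 0.0313 to 0.554 and 0.0118 to 0.554. With an estimated correlation chromosome 12 passed (0.0441) and chromosome 11 did not (0.0533). Both were lost without any single library other than wild type replicate 1 (0.0513 to 0.075). Chromosome 6 did not pass with the preset correlation (adjusted p = 0.0925) and passed with an estimated one (0.0243).

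The shifts had edges inside chromosomes. On chromosome 3, the 29 tested genes between 67.36 and 89.48 Mb had a median of -1.32. Their flanks, from 3.13 to 67.01 Mb (354 genes) and from 93.87 to 178.86 Mb (298 genes), had medians of -0.44 and -0.61. The 106 genes from 179.02 to 198.22 Mb had a median of 0.04. On chromosome 4, the 166 genes from 0.05 to 48.86 Mb had a median of 0.48 and the 352 genes from 51.84 to 177.68 Mb had -0.57. On chromosome 9, the 363 genes from 89.36 to 138.18 Mb had a median of 0.35. Falling segments also lay on chromosome 6 (110.1 to 170.58 Mb, -0.49), chromosome 10 (0.13 to 22.33 Mb, -0.50), chromosome 13 (75.28 to 100.59 Mb, -0.56), chromosome 5 (168.29 to 181.27 Mb, -0.34) and chromosome 7 (0.14 to 56.11 Mb, -0.29). On chromosome 19 the 52 genes from 32.68 to 36.00 Mb had a median of 0.62 and those from 36.01 to 58.60 Mb had -0.29. In all, 18 shifted segments held 3836 genes (27.1%), of which 69.6% changed, against 52.4% of genes outside them. Outside these segments 2950 genes rose and 2460 fell, 493 and 63 of them by at least 2-fold. In a separate fit without the genes of these segments, 2756 rose and 2688 fell. The 8 called gene lists remained called in that fit with the preset correlation but not with an estimated one (adjusted p of 0.188 to 0.384), and all 43 measured histone genes lay outside.

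**Figure D3:**
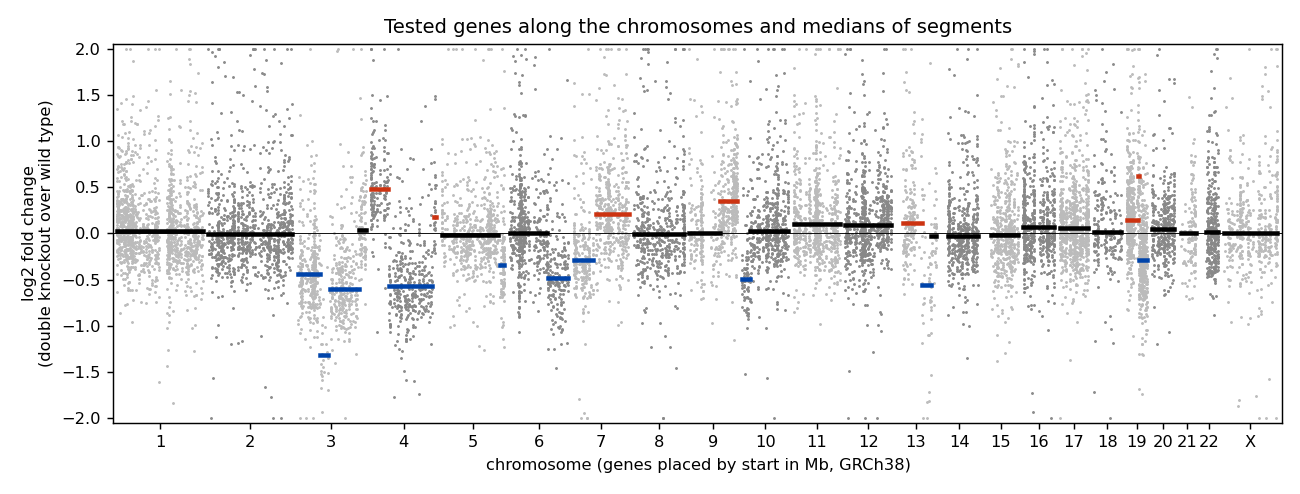
Log2 fold change (y axis, double knockout over wild type, drawn within 2 of zero) of each tested gene along the chromosomes (x axis, gene start in Mb, hg38). Horizontal bars are medians of segments, red where a segment shifted up, blue where it shifted down and black otherwise. The lowest bar, at -1.32, spans 67.36 to 89.48 Mb of chromosome 3.

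The spike-in RNA GFP took a slightly larger share of counts in the double knockout, whereas FLuc alone hardly differed. GFP had 48.1 ± 2.52 CPM of all counts in wild type and 54.4 ± 4.61 in double knockout (two-sided exact permutation p = 0.1). FLuc had 7.45 ± 1.69 and 7.69 ± 1.55 (exact p = 0.6). GFP and FLuc together had 55.5 ± 1.40 CPM of all counts in wild type and 62.1 ± 5.42 in double knockout (SD, n = 3 each), a difference of 6.63 CPM and a ratio of 1.12 (two-sided exact permutation p = 0.1, the smallest possible). Without double knockout replicate 2 the difference was 3.51 CPM, and spike-in scaling used all 6 libraries. Scaled to GFP and FLuc, the median of all genes was -0.10, against 0.01 with TMM, and 2133 genes rose and 4236 fell. Risen genes then made up 33.5% of changed genes, against 50.1% with TMM. All other fold changes given here are relative to TMM. Under this scaling the medians of ribosomal protein genes, glycolysis genes, neighbours of the targets and other AlkB dioxygenases turned from positive to negative. These medians were small, and the shift of all genes by itself takes them below 0. With the same scaling 7 instead of 22 S phase genes rose. Of the G2 and M phase genes 1 rose and 20 fell. This scaling rests on 316 to 440 GFP and FLuc counts per library, and it made the gene tests less precise. The log2 fold change of ALKBH5 went to -0.50 while its edgeR adjusted p rose from 2.74e-22 to 1.45e-07. A call lost under this scaling therefore need not be a change of direction.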

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

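The test of the S phase list for histone mRNAs, the shuffles of gene positions set against single chromosomes and the tests of GC content and exon length on parts of chromosomes 4 and 9 were chosen only after their results were seen, and the search for chromosome segments was written after the chromosome tests were seen. Intervals in this section are over genes taken as independent, not over libraries, so they can be too narrow.

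The Rluc spike-in entry held 2005 counts over the 6 libraries, although the labels name only GFP and FLuc as added RNAs. It was singled out because the labels do not name it and the TMM-scaled comparisons do not use it. Rluc had 49.1 ± 1.73 CPM in wild type and 53.7 ± 4.49 in double knockout (SD, n = 3 each, two-sided exact permutation p = 0.2).

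Genes of chromosomes 3, 4 and 9 moved together. Chance position was argued against by 100 shuffles of gene positions and the farthest segment of 30 or more genes that each gave on any chromosome. It was as far from 0 as the farthest segment of chromosome 3 in 0 shuffles, of chromosome 4 in 0 and of chromosome 9 in 1. GC content and exon length were argued against as the whole source. After a trend in both was removed, chromosome 3 kept a median of -0.44 (95% interval -0.477 to -0.411), the risen part of chromosome 4 0.49 (0.441 to 0.547), the fallen part of chromosome 4 -0.50 (-0.539 to -0.446) and the risen part of chromosome 9 0.31 (0.270 to 0.333). The medians of chromosomes 4 and 9 as wholes went from -0.29 to -0.24 and from 0.24 to 0.21. Different copy numbers of these segments in the cells compared may account for the shifts. Of genes of these chromosomes left out of the segment search, 89.3% lay on their segment's side (95% interval 87.6 to 90.8). That lay past the bound set for copy number, but any shift shared by neighbouring genes gives such a share. It therefore does not tell copy number from other causes. Over all shifted segments, with no genes left out, the share was 82.1%. RNA alone does not show copy number, and with all libraries of a group sharing a genotype, a difference between cell clones or parental lines and an effect of the knockout on these segments both stay open.

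More genes rose than fell by at least 2-fold, with a ratio of 3.39. Of the 194 that fell, 131 lay in shifted segments, and outside these segments 493 rose and 63 fell, a ratio of 7.83. Library size was argued against, since thinning all libraries to the smallest total gave a median ratio of 3.47. Scaling stays open, because spike-in scaling gave 1.71 (95% interval 1.48 to 1.98), between the bounds set for it. Total count scaling moved the ratio the other way, to 4.62, with 730 genes higher and 158 lower. Low counts were argued against as the whole source, because genes with a mean CPM of at least 5 gave 2.80 (2.25 to 3.51). That interval lay above the bound set for low counts as the source. The ratio passed the bound set against them, but its interval crossed that bound, so a smaller part stays open. The genes that rose had a median of 6.59 CPM against 11.9 for those that fell. An effect of losing the demethylases was not separated from these and may also contribute.

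Replication-dependent histone mRNAs were lower, with a median of -0.63. Lower recovery of short transcripts was argued against, since other protein-coding genes of up to 800 nt had a median of 0.065 (95% interval 0.016 to 0.103). Fewer cells in S phase stay open as a source. The S phase list had a median of 0.14 (0.09 to 0.19) with TMM, past the bound set against that source. But transcripts do not count cells, so a higher list does not show how many cells were in S phase. G2 and M phase genes were lower (median -0.18, of 31 measured 19 fell and 4 rose). With spike-in scaling the S phase median was 0.034 (-0.018 to 0.090), against -0.10 for all genes. This interval crossed 0, although it lay above the bound set for fewer cells in S phase. Relative to all genes the list median was 0.136 with spike-in scaling and 0.131 with TMM. Lower recovery of RNAs without a poly(A) tail was argued against as the whole source only by short noncoding RNAs taken as a set. Short noncoding RNAs had a median of -0.093 (-0.199 to -0.018), and this interval lay above the bound set for that recovery as the source. The median lay past the bound set against that recovery, but the interval crossed that bound. Cytoplasmic noncoding RNAs had a lower median of -0.21, with 2 of 7 fallen and 5 that did not pass. Nuclear-retained RNAs, a list that mixes RNA types, had -0.42, with 6 of 12 fallen. A part played by such recovery therefore stays open. A biological change in histone mRNA may be one explanation. It cannot be told apart here from a part played by recovery or by fewer cells in S phase.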

How the results depend on the processing

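The alternatives with Rluc in the spike-in scaling, without chromosomes 3, 4 and 9, and without shifted segments were chosen only after the data were seen. Of 2407 values of named genes under alternatives, 2328 kept direction and side of the threshold, 78 lost the threshold and 1 turned, UPF1 at -0.0022 with GFP and FLuc scaling. ALKBH5 lay between -0.43 and -0.37 and FTO between -0.96 and -0.86 without single libraries. Where no cause is named below, the cause was not tested. Scaling to GFP and FLuc gave 2133 genes higher, 308 at least 2-fold lower and 3 chromosomes, and scaling with Rluc gave 2406 genes higher and 3 chromosomes. Without a filter, camera called 15 lists and 2 chromosomes, losing chromosome 4 (adjusted p = 0.414), and the medians of other AlkB dioxygenases (-0.061), neighbours (-0.015), substrates (0.091), ribosomal proteins (-0.079) and TGF-beta targets (0.080) turned, relative to all genes. A mean CPM of at least 5 left 311 and 111 genes at least 2-fold higher and lower, since fewer genes were tested, and fibroblast markers turned to 0.062. Without shifted segments, which removes genes by construction, 2688 genes were lower, 69 at least 2-fold lower, and camera called 0 chromosomes (0 of 21 at an unadjusted p under 0.05, 13 with fry). There, other AlkB dioxygenases (-0.0033), ribosomal proteins (-1.1e-04), chromosome 3 (0.0089) and chromosome 9 (-0.018) turned. Without chromosomes 3, 4 and 9, 117 genes were at least 2-fold lower, camera called 0 chromosomes (4 at an unadjusted p under 0.05, 15 with fry), and ribosomal proteins (-0.0025) and fibroblast markers (0.023) turned. With replicate number as a block, 3 chromosomes were called. An estimated correlation left 0 lists called by camera (7 at an unadjusted p under 0.05, 21 with fry). The estimate was above the preset 0.01 for histone genes (0.586) and G2 and M phase genes (0.035). For the other called lists it was below 0, from -0.0526 for kidney tubule markers to -0.0071 for ATF4 targets. A larger correlation therefore was not what ended those calls. glmTreat counted 2029 genes higher and 1758 lower, since it tests against 1.2-fold rather than 2-fold. Without single libraries, 3 to 5 chromosomes were called, with 3 in each case except without wild type replicate 1, where chromosomes 11 and 12 remained (0.0513 to 0.075 without the others). Ribosomal proteins then ranged from -0.030 to 0.018, other AlkB dioxygenases from -0.043 to 0.046 and mitochondrial mRNAs from -0.109 to 0.029. The number of lists ranged from 8 to 12. Interferon genes passed without wild type replicate 1 (0.033), 2 (0.0237) or 3 (0.045) or double knockout replicate 2 (0.0363). Cholesterol and zinc finger genes passed without wild type replicate 2 (0.04996 and 0.0352) or 3 (0.045 each), and nuclear-retained RNAs without wild type replicate 2 (0.0239) or double knockout replicate 2 (0.0288). Without wild type replicate 1, calls were lost for ORC1 (adjusted p = 0.0783), SMCR8 (0.089), UPF1 (0.129) and MYO15A (0.194). Without wild type replicate 2 they were lost for TACC3 (0.0575), FMR1 (0.0681), ORC1 (0.0829), UPF1 (0.0975), FOSB (0.114) and RPGRIP1L (0.289). Without wild type replicate 3 they were lost for TACC3 (0.0577), ALKBH3 (0.06), MYO15A (0.0819) and BUB3 (0.261). Without double knockout replicate 1 they were lost for ALKBH3 (0.0568), VTRNA1-1 (0.0609), RPGRIP1L (0.0785) and BUB3 (0.0942). Without double knockout replicate 2 they were lost for ALKBH4 (0.052), ORC1 (0.0677), FOSB (0.0716), BUB3 (0.0738), MYO15A (0.0844), YTHDF1 (0.148), UPF1 (0.168) and RPGRIP1L (0.264). Without double knockout replicate 3 they were lost for VTRNA1-1 (0.0501), TACC3 (0.0517), FOSB (0.0847), MYO15A (0.131) and VTRNA1-3 (0.17). Genes or lists absent under an alternative gave no value, up to 52 genes without shifted segments. At this depth, small simulated changes were recovered in 26 of 50 genes, so small changes of scarce genes can be missed.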

Other observations

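The tests of gene lists outside shifted segments were chosen only after the data were seen. Further gene lists were measured, and none of those in this paragraph and the next passed as a set with the preset correlation, except under the alternatives named. Cytosolic ribosomal protein genes moved both ways, 23 of 80 rose and 30 fell, the same adjusted over the list alone (adjusted p = 0.451), but 5 rose and 28 fell with spike-in scaling. RPL9 rose by 0.69 in the part of chromosome 4 that rose, and RPS12 (chromosome 6) and RPSA (chromosome 3) fell by 0.71 and 0.66 in segments that fell. Their median was 0.01 and their mean -0.06, and camera gave the direction down. Of 62 translation factors, 17 rose and 26 fell, the same adjusted over the list alone (adjusted p = 0.390), but 4 rose and 27 fell with spike-in scaling. EIF4E, which binds the mRNA cap, fell by 0.77 (chromosome 4), EIF2A fell by 0.71 (chromosome 3) and EIF3G rose by 0.46 (chromosome 19). Of 61 oxidative phosphorylation subunits, 20 rose and 18 fell, the same adjusted over the list alone (adjusted p = 0.953), with COX6B1 at 0.65 (chromosome 19), ATP5ME at 0.58 (chromosome 4) and ATP5F1C at -0.39 (chromosome 10). With spike-in scaling 3 of these subunits rose and 15 fell. Each of these genes lies in a segment that moved in its direction. With the segment mean subtracted, RPL9 kept 0.17, RPS12 -0.31, RPSA -0.27, EIF4E -0.27, EIF2A -0.19, EIF3G 0.26 and ATP5ME 0.07. COX6B1 (-0.07) and ATP5F1C (0.03) turned. Of 13 mitochondrial mRNAs, 3 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.620), with MT-ND2 at 0.51, MT-CO1 at -0.31 and MT-CO2 at -0.24, and 2 rose and 6 fell with spike-in scaling. Of 22 cholesterol genes, 12 fell and 4 rose, against 13 and 4 adjusted over the list alone (adjusted p = 0.0588), and 12 fell and 2 rose with spike-in scaling. The list passed in 5 of 21 alternatives, among them limma voom (0.0177), DESeq2 (0.0119) and no filter (0.00518), in a range of 0.00518 to 0.235. SQLE fell by 0.80, MSMO1 fell by 0.84 (chromosome 4) and IDI1 fell by 0.53 (chromosome 10). Of 26 glycolysis and hypoxia genes, 12 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.181), and 8 rose and 5 fell with spike-in scaling. The list passed in 1 of 21 alternatives, DESeq2 (0.0248), in a range of 0.0248 to 0.591. NDRG1 rose by 1.17, ENO2 by 2.03 and GPI by 0.49 (chromosome 19). With the segment mean subtracted, MSMO1 kept -0.34 and IDI1 -0.11, and GPI turned to -0.23.

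Of 18 heat shock chaperones, 10 fell and 4 rose, the same adjusted over the list alone (adjusted p = 0.237), but 9 fell and 1 rose with spike-in scaling. Without the low-count filter chaperones (0.0463), translation factors (0.0470) and ribosomal protein genes (0.0463) passed, in ranges of 0.0463 to 0.523, 0.0470 to 0.701 and 0.0463 to 0.924. HSPB1 rose by 2.90 (chromosome 7), and HSPD1 and HSPA8 fell by 0.34 and 0.28. Their median was -0.12 and their mean 0.04, and camera gave the direction down. Of 25 genes of the unfolded protein response, 8 rose and 10 fell, the same adjusted over the list alone (adjusted p = 0.459), but 1 rose and 10 fell with spike-in scaling. CANX fell by 0.54 (chromosome 5), EDEM1 fell by 0.75 (chromosome 3) and HSP90B1 fell by 0.33. Of 342 numbered zinc finger genes, 63 rose and 123 fell, the same adjusted over the list alone (adjusted p = 0.0588), but 32 rose and 137 fell with spike-in scaling, with ZNF257 at 4.23, ZNF483 at 1.01 (chromosome 9) and ZNF146 at -0.69 (chromosome 19). Of these 342 zinc finger genes, 201 lie in shifted segments, against 27.1% of all genes on the chromosomes. Of the other 141, 25 rose and 34 fell in a fit without those segments (median -0.020, adjusted p = 0.574). The segments were found from these same fold changes, so leaving them out removes shifted genes by construction. A fall of the segments cannot be told apart here from a fall of zinc finger genes as a group. The whole list passed in 7 of 21 alternatives, in a range of 0.0151 to 0.574. Of 16 fibroblast markers, 5 rose and 7 fell, the same adjusted over the list alone (adjusted p = 0.837), with CDH2 at 1.02, VIM at 0.45 and SNAI2 at -1.23. VIM rose although its segment of chromosome 10 fell. Of 3 measured haematopoietic markers, 1 rose, CD8A by 0.96, the same adjusted over the list alone (adjusted p = 0.287). Of 13 WNT feedback targets, 2 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.390), with DKK1 at 1.45, NKD2 at 0.63 and LEF1 at -0.34 (chromosome 4). Of 14 TGF-beta and BMP targets, 3 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.837), with ID4 at 0.59, ID2 at 0.38 and SMAD6 at -0.45. Their median was -0.04 and their mean 0.04, and camera gave the direction down. Of 7 cytoplasmic noncoding RNAs, 2 fell, VTRNA1-1 by 0.65 and VTRNA1-3 by 0.21, the same adjusted over the list alone (adjusted p = 0.451). Genes of this paragraph with a chromosome given, other than VIM, lie in segments that moved in their direction. With the segment mean subtracted, LEF1 turned to 0.16. HSPB1 (2.65), CANX (-0.26), EDEM1 (-0.36), ZNF483 (0.60) and ZNF146 (-0.41) kept their direction.

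Splits of the 6 libraries into 3 and 3 number 10, which is too few for a share under 0.05. The real split was the only 1 of the 10 to give as many genes higher (4055), lower (4038), at least 2-fold higher (657) and at least 2-fold lower (194). The highest other split gave 0 of each in edgeR, with 64 to 117 genes at an unadjusted p under 0.05 (8658 in the real split) and 0 with limma voom (8017). Chance alone would give 709 genes at an unadjusted p under 0.05, more than these splits gave. Each other split mixes libraries of both groups, so the group difference enters the spread between libraries and calls of single genes become unlikely. The other splits therefore do not measure chance. For gene lists, 1 of the 10 splits gave as many as the real 8, and the highest other gave 7. For chromosomes, 1 of the 10 gave as many as the real 5, and the highest other gave 2. Set tests thus still made calls in mixed splits with 0 genes called. The counts of lists and chromosomes in these splits do not measure chance either.

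Outside shifted segments, interferon-stimulated genes (adjusted p = 0.0247), nuclear-retained RNAs (0.0318) and the substrates list (0.0423) also passed with the preset correlation. With an estimated correlation their adjusted p was 0.188, 0.403 and 0.231. Over all alternatives the ranges were 0.0211 to 0.235, 0.0239 to 0.494 and 0.0423 to 0.975.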
